A study of Arabidopsis thaliana with 12 samples.

How the data were processed

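Petioles of Arabidopsis thaliana plants were profiled on 12 Affymetrix ATH1 arrays, an expression array that reads each transcript with a set of short probes near its 3' end. Per the labels' protocols, plants grown to an age of 4 weeks in white light with a red to far-red ratio (R/FR) of 2.2 were kept for 2 h in that light or in light of R/FR 0.2, the ratio found under neighbouring leaves, with a mock spray or a spray of 0.5 mM salicylic acid (SA), a defence hormone. A biological replicate was a pool of 3 petiole pieces of about 5 mm from different plants, and 100 ng of its total RNA was labelled. The titles put 3 replicates in each of the 4 groups.

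The deposited values are log2 expression summaries per probe set, made by the authors with robust multi-array averaging (RMA), per the submitters' processing notes. The RMA software, its version and the probe-set definition are not given in the sources used here. RMA subtracts a model of the background, forces the arrays to a common distribution and summarises the probes of a set, so a change shared by most transcripts would be removed and dim probe sets are compressed toward the floor. The values ran from 0.46 to 11.37 and the array medians from 1.70 to 1.76. The hybridization controls, 4 transcripts spiked from 1.5 to 100 pM, rose by 1.03 to 1.11 log2 units per doubling, which fits no other log base. No background call per probe set was used here, and 54.9% of the features tested had a mean below 2. For arrays, the number of arrays limits the precision.

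Of 22810 probe sets, 64 controls were left out. Gene names came from a table of the platform's annotation, updated through the gene identifiers to the locus tags of the TAIR10.1 reference table, of which no coordinates are printed because no build is named for the array. Among the remaining 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed in the table used here and stay unnamed, though they were tested. The probe set with the highest mean over all arrays stood for each of the 146 genes with more than 1. This left 22589 features, of which 13356 had a gene name and 13286 of those a locus tag. No probe set with several genes is named.

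The 4 group means were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual degrees of freedom and 4.13 prior degrees of freedom. From this fit came the effect of SA in each light, the effect of low R/FR with each spray, their interaction (the SA effect in low R/FR minus that in high R/FR), and both average effects, 7 contrasts in all. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over the 22589 features, two-sided. Standard errors (SE) are those of the moderated fit, and SD is the spread of the 3 arrays of a group. These p-values measure the spread between the 3 pools of a group.

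The 23 gene lists, with 396 loci, were fixed before the data were examined, as were the design and the alternatives other than the place grouping and the name families. Only 55 of the 396 loci were measured by a named probe set, and 9 lists had at least 3 measured members. A member counts as measured where a named probe set matched its locus. Other members may still be read by unnamed probe sets, so they need not be absent from the array. Those 9 were tested with camera at a preset correlation of 0.01, which compares a list with all other features, with camera at a correlation estimated from the data, and with fry, which asks whether a list's genes moved one way on balance. P-values were adjusted over the 9 lists of a contrast. Where no gene passed in a contrast, the rule for naming genes took the 5 with the smallest unadjusted p among genes with a name, and members of a list could be named with it. Families of at least 8 genes sharing a symbol stem, 30 in all, were added after the data were seen.

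Similarity of arrays was the correlation of their deviations from the mean of all 12 arrays, and was compared within and between groups over all 15400 splits of the arrays into 4 groups of 3, an exact permutation test. The sample descriptions end in numbers that form 3 runs of 4 consecutive values. The place of an array in its run, from 1 to 4, was used as a second grouping after the arrays had been seen not to resemble each other within the titled groups. Differences between 3' and 5' control probe sets of actin, GAPDH and ubiquitin, 6 pairs in all, served as measures of RNA quality. They were tested by the same exact permutation and adjusted over the pairs. For the 2 comparisons that subtract the same 3 arrays, agreement in sign was set beside that of 100 simulations of unchanged groups at the observed spread, added after the data were seen. Random lists, 10000 per list and matched on mean expression in 20 bins, gave percentiles.

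Alternatives were the replicate number or the run as a block, eBayes with trend and robust settings, removal of the dimmest 30% of features, a second quantile normalization, subtraction of array medians, the mean of a gene's probe sets, array weights, a fold threshold of 1.5, a fit of only the arrays compared, and leaving out each array in turn. The scripts were tested on simulated log2 data with the observed means and spread, in which 200 of 22589 genes were changed in each of 20 runs. For the SA effect in high R/FR, the fit called 50.2% of the genes changed by 1.5-fold, 86.5% of those changed by 2-fold and 98.4% of those changed by 4-fold, with 5.15% false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.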

Results

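Gene expression was measured in petioles of Arabidopsis plants held for 2 h in light of high or low R/FR and sprayed with SA or a mock solution, to ask how the shade signal and the defence hormone act on each other. Each of the 4 groups had 3 arrays. Array medians lay between 1.70 and 1.76 on the log2 scale and 22589 features were tested, of which 13356 carried a gene name. Values are log2 values of arrays as labelled in the titles, with n = 3 in each group.

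Arrays with the same label did not resemble each other more than arrays with different labels. Correlations of the arrays' deviations averaged -0.15 within labelled groups and -0.08 between them (exact permutation p = 0.838). The closest match of an array carried the same label for 1 of 12 arrays. After the data were seen, the arrays were also sorted by their place in the 3 runs of 4 description numbers, and 11 of 12 arrays matched best an array at the same place. Within places the correlation averaged 0.17 and between places -0.15 (exact permutation p = 6.494e-05, the smallest that the 15400 splits can give). The places were picked from the similarity of the same arrays, so this p restates it. The first principal component held 26.3% of the variance. Labelled groups accounted for 11.45% of its variance (exact permutation p = 0.778). Places accounted for 97.89% of it, which also restates the similarity from which they were picked. For these reasons each group is described as the arrays labelled so.

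**Figure D1:**
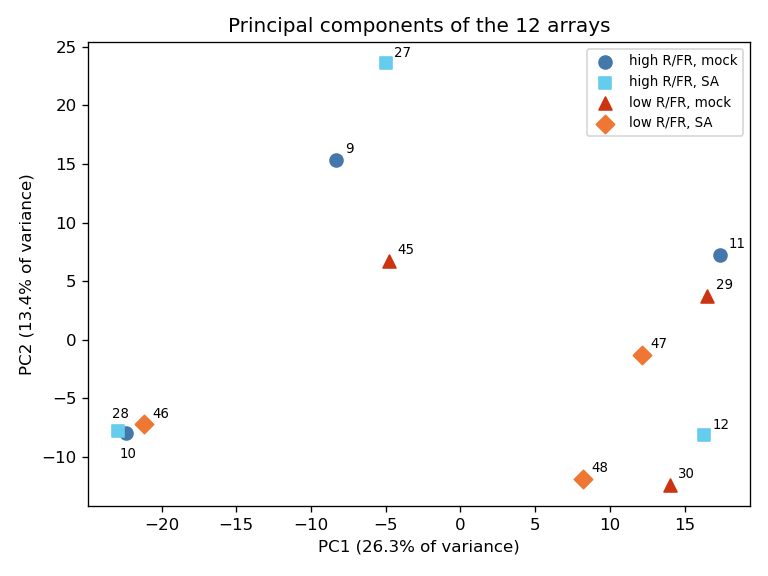
First against second principal component of the 12 arrays, in units of the component scores, with colour and marker for the labelled group and the description number beside each point. The first component held 26.3% and the second 13.4% of the variance, and every labelled group is spread along the first.

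IAA29, an early shade-induced Aux/IAA repressor, shows this spread. Among the arrays labelled high R/FR with mock spray it ran from 1.95 to 5.41, and its mean was 3.23 ± 1.90 (SD). The arrays labelled low R/FR with mock spray ran from 2.73 to 5.47, with a mean of 4.54 ± 1.56 (SD). GH3.5, which conjugates auxin to amino acids, ran from 1.66 to 4.198 in the first of these groups and from 2.54 to 4.62 in the second. EXO, a cell expansion gene, ran from 5.42 to 7.40 and from 5.59 to 7.83. The glycolytic reference gene GAPC2 stayed between 10.27 and 10.41 in all 12 arrays. The SDs of IAA29 with SA spray were 2.00 in high R/FR and 2.34 in low R/FR.

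**Figure D2:**
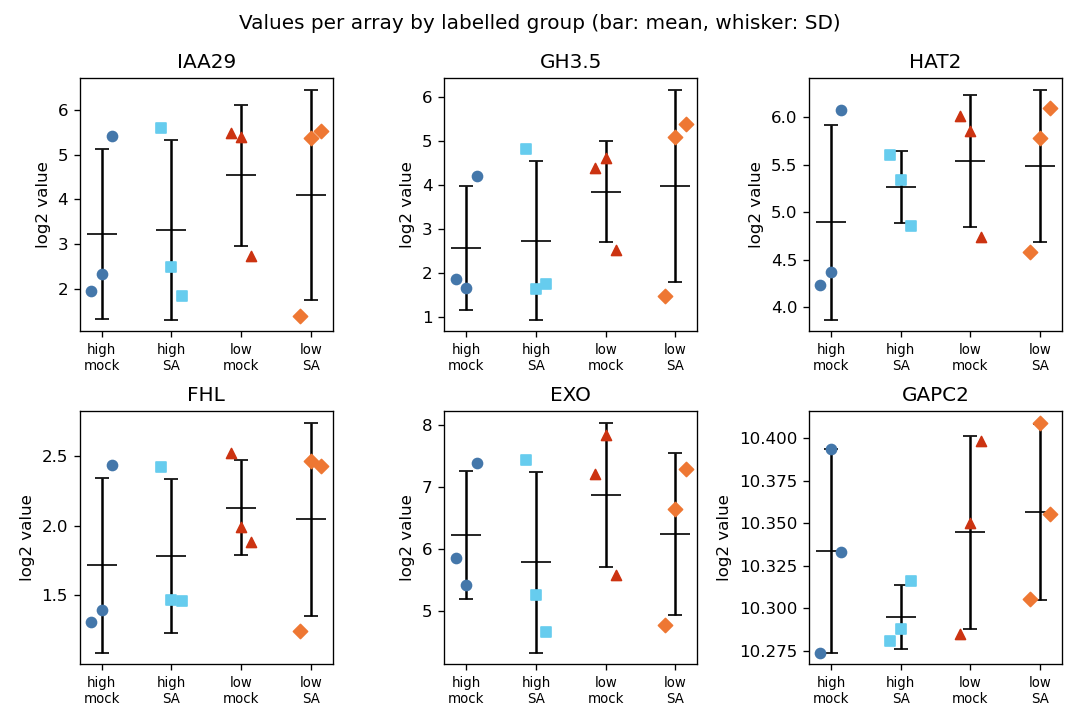
Log2 values of 6 genes per array, by labelled group, with points for the 3 arrays, a bar for the mean and a whisker for the SD. IAA29 spans 1.95 to 5.41 in the arrays labelled high R/FR with mock spray, while GAPC2 stays between 10.27 and 10.41 over all arrays.

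The effect of SA in high R/FR asks what the hormone does in unshaded petioles. No gene rose or fell past the threshold. Of the 25 SA-linked defence genes 2 had a named probe set, and neither passed. The others may be among the unnamed probe sets. GRXC9, a glutaredoxin that acts in SA signalling, was at 1.41 ± 0.32 (SD) with mock spray and 1.53 ± 0.26 with SA. SAG101, a partner of the immune regulator EDS1, was at 1.38 ± 0.38 and 1.45 ± 0.19. The means of both genes lay below the array medians of 1.70 to 1.76, near the floor of the array. A missing difference there does not show that they failed to respond. WRKY53, a transcription factor of defence and senescence, was at 2.34 ± 0.06 and 2.40 ± 0.52, and 0 of the 3 WRKY genes passed. Of 6 glutathione transferases 0 passed over all genes, and 1 passed when adjusted over the list alone. This was GSTU22, which was at 0.90 ± 0.09 with mock spray and 1.28 ± 0.12 with SA (log2 difference 0.39, SE 0.09, adjusted p = 0.00675 over the list alone and 0.939 over all genes, limma), a level near the floor of the array. Among 5 glycosyltransferases and other detoxification enzymes, UGT73B4 differed by -0.27 (SE 0.10) and UGT87A2 by 0.16 (SE 0.36), and 0 passed.

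Other lists gave no member past the threshold over all genes in this comparison. The gibberellin receptor gene GID1B differed by 0.22 (SE 0.08) and passed only when adjusted over the list alone, a list with 2 measured members (adjusted p = 0.0422, limma). Its values over all arrays lay between 0.91 and 1.25, near the floor of the array. Of the receptor-like and immune kinases, BIK1 differed by 0.20 (SE 0.14) and the receptor gene EFR, also near the floor, by 0.05 (SE 0.09). In the endoplasmic reticulum list, the chaperone gene ERDJ3B differed by -0.10 (SE 0.11) and the stress regulator bZIP60 by -0.02 (SE 0.11). PDF1.2A, a defensin of the jasmonate pathway, was at 3.03 ± 2.62 (SD) with mock spray and 1.84 ± 1.25 with SA, so its difference of -1.19 (SE 0.97) was within the error. The 4 measured reference genes, which are used to normalise PCR, moved up on balance by a mean of 0.13 (fry adjusted p = 0.0127), with 3 of 4 above 0. Camera did not single them out (adjusted p = 0.556 with the preset correlation and 0.851 with an estimated correlation).

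The 5 named genes with the smallest p, none of which passed, were NOL, a subunit of chlorophyll b reductase, with a difference of 0.54 (SE 0.11), AT1G20823 with -0.74 (SE 0.15), AT3G47940 with -0.56 (SE 0.12), AT1G55460 with -0.59 (SE 0.13) and AT1G23750 with 0.51 (SE 0.11). Limma gave 0 genes, with a smallest adjusted p of 0.939. At an unadjusted p under 0.05 there were 1142 genes, against 1129 expected by chance. Leaving out replicate 1 of the arrays labelled high R/FR with mock spray gave 5 genes: AT5G59170 higher, AT3G23450, the chloroplast ribosomal gene rps18 and 2 unnamed probe sets lower with SA, named after their values were seen.

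A control for RNA quality moved with the labels. The GAPDH 3' minus 5' difference was 1.18 ± 0.10 (SD) in the arrays labelled high R/FR with mock spray and 0.64 ± 0.11 in those with SA. It was 0.91 ± 0.07 in low R/FR with mock spray and 0.87 ± 0.04 with SA. It differed between the labelled groups (exact permutation p = 0.0003247, adjusted 0.00195 over the 6 control pairs). The other 5 pairs gave adjusted p from 0.105 to 0.808 by the same exact permutation, the second GAPDH pair 0.513.

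**Figure D3:**
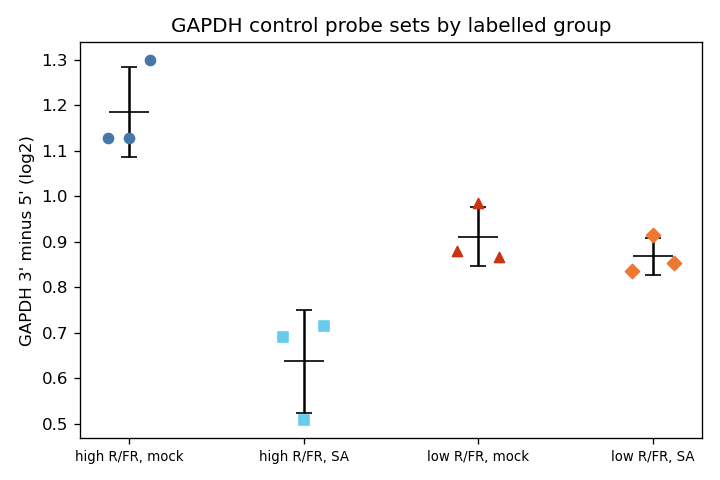
GAPDH 3' minus 5' difference in log2 units per array and labelled group, with points for arrays, a bar for the mean and a whisker for the SD. The means were 1.18, 0.64, 0.91 and 0.87.

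The effect of low R/FR with mock spray asks which genes the shade signal changes in petioles without added hormone. No gene passed, although growth-related lists had differences mostly above 0. Of the 4 early shade-avoidance genes 0 passed and 3 were above 0. IAA29 differed by 1.301 (SE 1.309, 95% interval from -1.55 to 4.15), HAT2, a homeodomain transcription factor, by 0.64 (SE 0.51) and FHL, which carries phytochrome A into the nucleus, by 0.42 (SE 0.39). YUC2, an auxin synthesis gene, differed by -0.04 (SE 0.11). All 5 auxin-responsive genes were above 0 with 0 passing, among them GH3.5 with 1.28 (SE 1.12), IAA30 with 0.74 (SE 0.46) and GH3.3 with 0.17 (SE 0.27). The arrays of these groups differ in place, so these differences mix light and place. At place 1, IAA29 was at 1.95 with high and 2.73 with low R/FR, and at place 3 at 5.41 and 5.47. The remaining arrays, at place 2 with high and place 4 with low R/FR, were at 2.34 and 5.401. GH3.5 was at 1.86 and 2.54 at place 1, 4.198 and 4.399 at place 3, and 1.66 and 4.62 in the remaining arrays. Each value is 1 array.

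As a list, the 5 cell wall loosening genes were higher in the arrays labelled low R/FR with mock spray (camera adjusted p = 0.0476), with 5 of 5 above 0 and 0 passing singly. The call was lost with an estimated correlation (adjusted p = 0.396), with the replicate block, with array weights, and when any 1 of 6 arrays was left out. These were replicates 1 and 2 labelled high R/FR with mock spray, replicate 1 labelled high R/FR with SA, replicates 1 and 2 labelled low R/FR with mock spray and replicate 3 labelled low R/FR with SA. The adjusted p fell to 0.00269 without replicate 3 labelled high R/FR with mock spray, to 0.0113 without replicate 3 labelled low R/FR with mock spray and to 0.0239 without replicate 1 labelled low R/FR with SA. Of the arrays labelled low R/FR with mock spray 2 of 3 were at places 3 and 4, against 1 of 3 of those labelled high R/FR with mock spray. EXO, EXPA8 and XTH19 also differed by place (moderated F test, adjusted p = 4.148e-05, 0.0258 and 0.0441). XTH19, a xyloglucan endotransglucosylase, differed by 1.197 (SE 0.48), EXO by 0.65 (SE 0.83), and the expansin genes EXPA8 by 0.58 (SE 0.53) and EXPA4 by 0.50 (SE 0.18). XTH16 differed by 0.02 (SE 0.39). The arrays of these groups shared 0 of the 3 runs of description numbers, so the run and the light cannot be compared within a run. With the run as a block, the cell wall list kept its call (adjusted p = 0.00808) and the auxin-responsive list was also higher (adjusted p = 0.0125). The run effects in that fit rest on the groups that span 2 runs, high R/FR with SA and low R/FR with mock spray. Their runs also differ in place, with place 4 against 1 and 2, and places 3 and 4 against 1. Run and place cannot be told apart in these calls. Without the block the auxin-responsive list did not pass (adjusted p = 0.144 with the preset and 0.641 with an estimated correlation), and the estimated correlation was not run with the block.

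**Figure D4:**
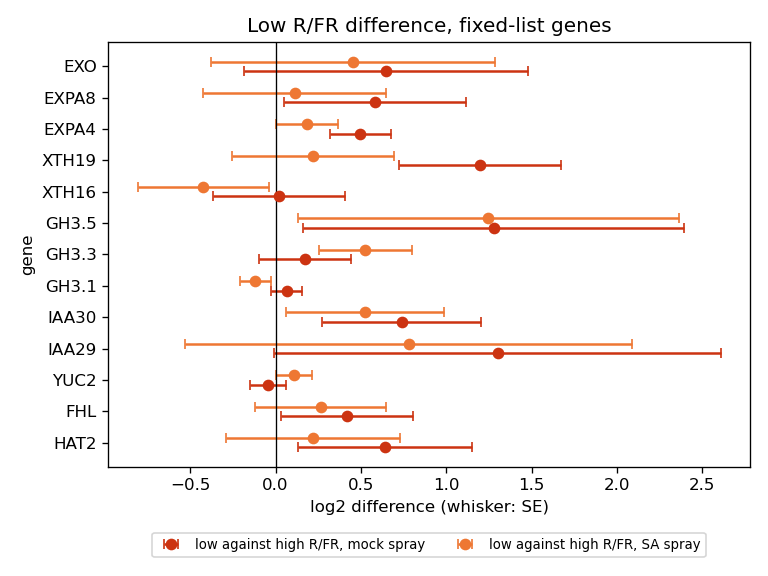
Log2 difference between arrays labelled low and high R/FR for the measured early shade-avoidance, auxin-responsive and cell wall loosening genes, with mock spray and with SA spray, and whiskers for the SE. With mock spray IAA29 lies at 1.301 with an SE of 1.309.

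Lists of other tissues and pathways had 0 members past the threshold over all genes with low R/FR and mock spray. Of 3 photosynthesis genes, the antenna protein gene LHCB4.1 differed by 0.11 (SE 0.09) and the Rubisco activase gene RCA by -0.0038 (SE 0.10). The stomatal genes SPCH, MUTE and FAMA, the measured part of the epidermis, trichome and guard cell markers, differed by -0.10 (SE 0.10), 0.04 (SE 0.12) and -0.02 (SE 0.13). SWEET11, a sucrose exporter of the phloem and the sole measured vascular marker, was at 1.35 with high and 1.08 with low R/FR, near the floor of the array. It differed by -0.27 (SE 0.09), and as a list of 1 gene its p needs no adjustment (limma adjusted p = 0.00986 over the list alone). Of the 55 measured members of all lists 3 had an unadjusted p under 0.05 here, with 2.75 expected by chance. The anthocyanin genes DFR and UF3GT differed by 0.93 (SE 0.74) and 0.38 (SE 0.41). In lists with 1 measured member, COR15A for abscisic acid and drought differed by -0.10 (SE 0.25), ZAT10 for touch and wounding by 0.09 (SE 0.16), HSP22.0 for heat shock by 0.02 (SE 0.10), GI for the clock by 0.04 (SE 0.20) and UGT74B1 for glucosinolates by -0.14 (SE 0.25). In the ethylene and the sugar starvation lists 0 members had a named probe set.

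The 4 reference genes were higher on balance, by a mean of 0.13 (fry adjusted p = 0.00742), with 4 of 4 above 0. This comparison and the SA effect in high R/FR subtract the same 3 arrays, so they do not repeat each other: 3 of 4 reference genes had the same sign in both (75%), against 66% in simulated unchanged groups. Over all features the share was 69.0% against 66.7% simulated, and the covariance 0.0151 against 0.0153. In these arrays the GAPDH 3' minus 5' difference was 0.91, against 1.18 in those labelled high R/FR with mock spray. Camera gave an adjusted p of 0.144 and, with an estimated correlation, 0.396 for this list. The 5 named genes with the smallest p, none passing, were AT1G79660 with a difference of 0.63 (SE 0.11), AT5G06060 with -0.44 (SE 0.09), AT3G47940 with -0.57 (SE 0.12), the cyclophilin gene CYP59 with -0.40 (SE 0.09) and AT1G31300 with 0.49 (SE 0.11). Limma gave 0 genes (smallest adjusted p 0.925) and 1196 at an unadjusted p under 0.05. Without replicate 1 of the arrays labelled high R/FR with mock spray, 2 unnamed probe sets passed, both lower in low R/FR.

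The effect of SA in low R/FR asks what the hormone does in shaded petioles. No gene passed. Cell wall loosening genes lay below 0 in 4 of 5 cases, with XTH19 at a difference of -0.80 (SE 0.48), XTH16 at -0.74 (SE 0.39) and EXO at -0.63 (SE 0.83), and the list did not pass (camera adjusted p = 0.428). These groups differ in place, so these differences mix spray and place. At place 3 XTH19 was at 4.70 with mock and 4.39 with SA spray, and at place 4 at 3.76 and 3.63. The remaining arrays, at place 1 with mock and place 2 with SA spray, were at 4.41 and 2.46. XTH16 was at 4.18 and 4.17 at place 3, 4.86 and 4.26 at place 4, and 4.64 and 3.03 in the remaining arrays. EXO was lower with SA in each of these pairs. Each value is 1 array. IAA29 differed by -0.44 (SE 1.31) and HAT2 by -0.05 (SE 0.51). GRXC9, near the floor, was at 1.22 ± 0.05 (SD) with mock spray and 1.51 ± 0.26 with SA, and WRKY53 at 2.32 ± 0.19 and 2.32 ± 0.07. GSTU16 differed by 0.52 (SE 0.27) and UGT87A2 by 0.71 (SE 0.36). SWEET11 was higher with SA by 0.30 (SE 0.09), past the threshold only over its list of 1 gene (limma adjusted p = 0.00464 over the list alone). The 5 named genes with the smallest p were AT3G59110 with -0.39 (SE 0.08), the glycosyltransferase gene UGT84A3 with 0.61 (SE 0.13), AT2G39020 with 0.47 (SE 0.10), AT1G14300 with 0.48 (SE 0.11) and AT1G48330 with 0.53 (SE 0.13). Limma gave 0 genes (smallest adjusted p 0.9997) and 686 at an unadjusted p under 0.05.

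The effect of low R/FR with SA spray asks what the shade signal does when the hormone is present. No gene passed, and no list did by camera (smallest adjusted p 0.701). All 4 early shade-avoidance genes lay above 0, with IAA29 at a difference of 0.78 (SE 1.31), FHL at 0.26 (SE 0.39) and HAT2 at 0.22 (SE 0.51). Of 5 auxin-responsive genes 4 were above 0, with GH3.5 at 1.25 (SE 1.12) and GH3.3 at 0.53 (SE 0.27). EXO differed by 0.46 (SE 0.83) and XTH19 by 0.22 (SE 0.48). With the run as a block, 3 lists were higher, the auxin-responsive (camera adjusted p = 0.0135), cell wall (0.0407) and early shade-avoidance genes (0.0411), all at the preset correlation, although these groups also shared 0 runs. As with mock spray, no fit of the labelled groups held both run and place, so they were not told apart in these calls. Without the block all 3 lists had an adjusted p of 0.889 with an estimated correlation. Of the arrays labelled low R/FR with SA 2 of 3 were at places 3 and 4, against 1 of 3 of those labelled high R/FR with SA. At place 2, IAA29 was at 1.86 with high and 1.395 with low R/FR, and at place 4 at 5.600 and 5.532. GH3.5 was at 1.76 and 1.48 at place 2, and at 4.82 and 5.39 at place 4. Each value is 1 array. The 5 named genes with the smallest p were AT3G48970 with 0.52 (SE 0.10), AT1G14300 with 0.52 (SE 0.11), BUG22 with -0.42 (SE 0.09), AT1G56300 with 0.79 (SE 0.16) and NOL with -0.52 (SE 0.11). Limma gave 0 genes (smallest adjusted p 0.9998) and 749 at an unadjusted p under 0.05.

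The interaction asks whether the SA effect differs between the lights. No gene passed. IAA29 had an interaction of -0.52 (SE 1.85, 95% interval from -4.55 to 3.51), which leaves room for large differences in either direction. All 5 cell wall genes were below 0, with XTH19 at -0.98 (SE 0.67) and a camera adjusted p of 0.290 for the list. The 4 groups differ in place, so the interaction mixes place with the SA effects. GSTU16 was at 0.51 (SE 0.39) and UGT87A2 at 0.55 (SE 0.51). The reference genes moved on balance, by a mean of -0.18 (fry adjusted p = 0.015, camera adjusted p = 0.817 with an estimated correlation), with TIP41L at -0.40 (SE 0.17). SWEET11, near the floor in all groups, was at 0.44 (SE 0.12), past the threshold over its list of 1 gene (limma adjusted p = 0.00421 over the list alone) and not over all genes (adjusted p = 0.997). The 5 named genes with the smallest p were AT1G14300 with 0.93 (SE 0.15), BUG22 with -0.65 (SE 0.12), AT2G39020 with 0.71 (SE 0.15), AT2G40460 with 0.77 (SE 0.17) and AT3G47940 with 0.75 (SE 0.17). Limma gave 0 genes (smallest adjusted p 0.997) and 917 at an unadjusted p under 0.05.

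Averaged over the lights, arrays labelled SA differed from those labelled mock in 0 genes (limma, smallest adjusted p 0.999, 856 at an unadjusted p under 0.05). Averaged over the sprays, arrays labelled low R/FR differed from those labelled high R/FR in 0 genes (limma, smallest adjusted p 0.974, 996 at an unadjusted p under 0.05). With no gene called in either, the overlap of the average effects and the interaction over called genes were not computed. The median SE of a pairwise log2 difference was 0.125, and 1129 features would pass an unadjusted p under 0.05 by chance in each contrast.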

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

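The SA effect on the 4 measured reference genes differed between the lights by the interaction test of the labelled groups. Its mean was 0.13 in high R/FR and -0.05 in low R/FR, and fry gave an adjusted p of 0.015 for the difference of -0.18, which was below 0 for 3 of 4 genes. Camera did not single the list out (adjusted p = 0.290 with the preset correlation and 0.817 with an estimated correlation). The GAPDH 3' minus 5' difference also moved across these groups, at 1.18 and 0.64 with mock and SA spray in high R/FR and 0.91 and 0.87 in low R/FR, and whether RNA quality accounts for the difference was not tested.

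SWEET11, the sole measured vascular marker, had an SA effect of -0.13 (SE 0.09) in high R/FR and 0.30 (SE 0.09) in low R/FR. The difference of 0.44 (SE 0.12) had a limma p of 0.00421, adjusted over its list of 1 gene alone, and an adjusted p of 0.997 over all genes. Its group means, from 1.08 to 1.39, lie near the floor of the array. Of the 55 measured list members 3 had an unadjusted p under 0.05 in the interaction, with 2.75 expected by chance.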

How the results depend on the processing

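The place grouping and its recounts were chosen after the data were seen. Of 151 recounted gene counts for the 7 contrasts, 2 were above 0. Both came from leaving out replicate 1 of the arrays labelled high R/FR with mock spray. Leaving out single arrays gave 0 to 5 genes for SA in high R/FR and 0 to 2 for low R/FR with mock spray, and the cause was not tested. At an unadjusted p under 0.05 the counts over all alternatives ran from 418 to 1915. With the replicate block every contrast kept 0 genes. The replicate numbers did not pair the arrays: 18 same-number pairs of arrays correlated by -0.09 on average (-0.42 to 0.19), and 0 of 12 arrays matched best one with its own number. Over 5 contrasts the list test at the preset correlation gave 1 call, counted per list and contrast. The replicate block, array weights and an estimated correlation each gave 0, the run as a block gave 5, and leaving out single arrays gave 0 to 4, the highest without high R/FR, mock replicate 3. The cause was not tested. Of 2345 values of named genes under the other alternatives 147 moved by more than 1 SE and 88 changed sign, and of 3600 with an array left out 77 moved so and 245 changed sign, with 0 past the threshold over all genes. Grouped by place, 723 to 871 genes differed under the other alternatives and 478 to 780 with an array left out. The count fell from 731 to 478 without high R/FR, SA replicate 3 and to 480 without low R/FR, SA replicate 1. The overlap and the interaction over called genes had no value under any alternative, since neither average effect called a gene. Dim signal limits what can be seen, with 54.9% of features at a mean below 2.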

Other observations

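The families by name, the place grouping and the compression tests were chosen after the result they bear on was seen. So were the tissue test, the simulated shared arrays, the choice of the 18 hybridization control probe sets and the counts of other splits. The tests by place were too, apart from those named next. The tests on the shade-avoidance and SA-linked lists, the spiked controls, RNA quality and the number of arrays were set before theirs. All but the last use the place grouping, which had already been picked from these arrays.

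Chloroplast-encoded genes, 69 in all, were lower in the arrays labelled high R/FR with SA than in those with mock spray by a median of -0.18, with 51 of 69 below 0 (camera adjusted p = 5.035e-07 over 30 families, 0.832 with an estimated correlation). In low R/FR with mock spray the median was -0.13, with 48 of 69 below 0 (adjusted p = 0.0008, 0.845 with an estimated correlation). Ribosomal RPS genes, of which 8 of 9 are also chloroplast-encoded and so are not separate evidence, were lower in the same comparisons, by medians of -0.27 and -0.26 with 8 of 9 below 0 in each (adjusted p = 8.489e-05 and 0.0008, 0.717 and 0.530 with an estimated correlation). The GAPDH 3' minus 5' difference was also lower in these arrays, at 0.64 and 0.91 against 1.18. Also by camera at the preset correlation, the NAD family was lower in both comparisons (medians -0.11 and -0.10, adjusted p = 0.0461 and 0.038, 0.569 and 0.336 with an estimated correlation), and in low R/FR with mock spray the genes with the CYP stem were lower (median -0.12, adjusted p = 0.00477, 0.336 estimated) and the EXPA expansin family higher (median 0.18, adjusted p = 0.038, 0.530 estimated). The CYP genes share a symbol stem only, and the cyclophilin gene CYP59 is among them. EXPA4 and EXPA8 are also in the cell wall list. Both comparisons subtract the same 3 arrays labelled high R/FR with mock spray, so a shift in those arrays alone would move them together. The sign was the same in both for 58 of 69 chloroplast-encoded, 9 of 9 RPS and 6 of 8 NAD genes (84.1%, 100% and 75%), against 66.4%, 67.3% and 67.2% in 100 simulations of unchanged groups against shared arrays. The simulations drew each gene apart, so they leave out correlation between genes. Over all features the covariance was 0.0151 observed and 0.0153 simulated. With an estimated correlation 0 of 30 families passed in any contrast tested, and by the preset one 0 passed in the other pairwise comparisons or the interaction.

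By place in the runs of description numbers, 731 genes differed in the moderated F test (limma), against 0 by label, and 339 of them had a name. With the run as a block there were 837. IAA29 averaged 2.39, 1.86, 5.42 and 5.51 at places 1, 2, 3 and 4, with 3 arrays each (adjusted p = 5.655e-07), and its 3 values at place 3 lay between 5.37 and 5.47. GH3.5 averaged 2.02, 1.63, 4.56 and 4.95 (adjusted p = 6.32e-06), and EXO 5.58, 4.96, 7.09 and 7.52 (adjusted p = 4.148e-05). HAT2 averaged 4.77, 4.60, 5.96 and 5.85 (adjusted p = 0.00242). GSTU16 averaged 3.04, 3.78, 3.00 and 3.15 (adjusted p = 0.0421). Among the fixed lists, 4 of 5 auxin-responsive genes (Fisher's exact test, adjusted p = 1.799e-05), 3 of 4 early shade-avoidance genes (0.000286) and 3 of 5 cell wall genes (0.000468) differed by place, and 0 of 4 reference genes did. IAA29 counts in both the auxin-responsive and the shade-avoidance lists. The places were picked from the similarity of these same arrays, and genes of a list can vary together. These p-values are therefore not independent evidence that a list differs by place. Between pairs of places the counts were 155 for places 1 and 2, 194 for 1 and 3, 268 for 1 and 4, 850 for 2 and 3, 610 for 2 and 4, and 0 for 3 and 4. No light or spray is assigned to a place here.

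The labelled groups gave 0 genes in each of 7 contrasts. No fit of the labelled groups had place as a block, so differences between places stayed in the spread of these fits. Simulations of the SA effect in high R/FR called 98.4% of 4-fold and 50.2% of 1.5-fold changes at this number of arrays. The simulations added the full change to features at any level, dim ones included, and drew each gene apart. Their rates can therefore be too high for dim features. The simulations also do not bound genes with a wide spread, such as IAA29 with an SE of 1.309 against a median SE of 0.125. So too few arrays stays open for these, for dim features and for small changes. Compressed values are argued against at the level of the spiked controls, which rose by 1.065 log2 units per doubling between means of 4.05 and 10.73. Compression stays open for the 77.6% of features with a mean below the dimmest of these. A candidate explanation is that titles and arrays are out of step. By place 731 genes differed, against a highest of 323 in the other splits of 100 drawn, but the places were picked from the similarity of the same arrays, so this count restates it. The median F by place was 23.54 for the shade-avoidance genes and 1.55 for the 16 SA-linked genes, against 95th percentiles of 3.503 and 1.40 for matched random lists and medians of 0.60 and 0.84 by label. The 16 are 2 defence genes, 3 WRKY genes, 6 glutathione transferases and 5 detoxification enzymes. Singly, 1 of the 6 glutathione transferases differed by place, and 0 of the WRKY and detoxification genes did. A plain mismatch alone would not predict that a control differs by label. Of 6 control pairs 1 did, a GAPDH 3' minus 5' difference (exact permutation p adjusted over the pairs 0.00195). By place it did not pass the threshold (exact permutation, unadjusted p = 0.720). But each labelled group holds successive description numbers, so a difference that follows the order of these numbers would look the same. This pair therefore cannot decide about a mismatch. The second GAPDH pair did not pass by label (adjusted p = 0.513), nor did the actin pairs (0.752 and 0.808) or the ubiquitin pairs (0.257 and 0.105). Whether the titles or the value columns would be the part out of step cannot be settled from these values, and the hypothesis was found and tested on the same arrays.

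The differences by place may have technical sources, and 1 of 100 splits, the grouping by place itself, gave as many genes. That grouping had been picked from the data, so this does not exclude chance. The hybridization controls argue against an effect of array position shared by bright features. Of their 18 probe sets, all with a mean of at least 3.87, 0 passed by place (moderated F test, smallest adjusted p 0.962), and their place means ranged over at most 0.44. EXO, with place means from 4.96 to 7.52, ranged over 2.57. IAA29 ranged over 3.65, but its place means of 1.86 and 2.39 lie below the level of these controls. Over all 45 bacterial and phage control probe sets, many of them near the floor, 0 passed as well (smallest adjusted p 0.958). For dim features a position effect stays open. Effects by place of steps before these controls were added also stay open, since the controls cannot show them. RNA quality gave no difference by place past the threshold in the actin and GAPDH pairs set for this test (lower exact permutation p = 0.352), and over all 6 pairs the lowest was 0.0928 (adjusted 0.557). A tissue difference between petiole pieces stays open, because the median F of 0.68 (95th percentile 2.00) rests on 7 measured vascular, epidermal and photosynthetic genes. A difference in treatment between places also stays open. The shade-avoidance and SA-linked lists above both exceeded their 95th percentiles by place. These tests cannot decide it, because the grouping was picked from the same arrays. The random lists were also matched on mean expression and not on spread. The labels assign no treatment to a place, so no direct test was possible.

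For the 4 pairwise comparisons, 10 of 10 splits of the 6 arrays gave as many genes as the real one, and 10 splits are too few for a share under 0.05. The real count was 0 in each, which any split equals or exceeds, and the highest of the other splits was 0, 0, 0 and 22. The 22 came for low R/FR with SA spray from setting arrays at places 3 and 4 against arrays at places 1 and 2, while the one split of the mock arrays that did the same gave 0. For the interaction and both average effects, 100 of 100 splits gave as many genes as the real count of 0. Any split does so, and these counts say nothing about chance. The highest of the others was 592, 1 and 1. The split with 592 and the split with 323 also kept arrays at places 1 and 2 apart from those at 3 and 4. So many genes point to some structure among the samples, but these splits were looked at for their high counts, and their tie to place restates the similarity of the arrays by place.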
